A study of Homo sapiens with 16 samples.

How the data were processed

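RNA of SH-SY5Y cells was hybridised to 16 single-colour (Cy3) Agilent microarrays, 1 array per sample. Per the labels, each sample is an independent experiment, and the 16 samples form 4 groups of 4 replicates: control or 6-OHDA, each at 12 h or 18 h. The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1, and per the file headers the processed signal and the raw median signals are intensity values of single spots. The processed signal is already background-subtracted and detrended within an array, with no adjustment between arrays. The deposited series matrix holds the authors' own values of the same spots on a log2 scale. For replicates 1 to 4 its columns had medians of 5.26, 5.23, 5.24 and 5.24 in control cells at 12 h, 5.25, 5.23, 5.24 and 5.25 in 6-OHDA cells at 12 h, 5.24, 5.24, 5.24 and 5.23 in control cells at 18 h, and 5.24, 5.24, 5.25 and 5.24 in 6-OHDA cells at 18 h. The columns had near-equal distributions, and they correlated across spots with the log2 processed signal at 0.978 to 0.987 and with the log2 raw median signal at 0.995 to 0.999. The authors name limma, with no version. Their background step, if any, stays unknown. The matrix is not centred per gene and runs in the direction of the signal.

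Each array held 60901 non-control spots. Spots with an outlier mark, 123 to 201 per array, were left out, and the log2 processed signals of the spots of a probe were averaged. Values are this log2 signal minus the array's 75th percentile over all its probes. A probe was kept when it was well above background on all 4 arrays of at least 1 group, which left 25238 of 58201 probes. Probes were named by matching the accession in the files, without its version, to the RefSeq table supplied for this work. In that match 31104 probes (53.4%) received 1 of 22439 symbols, and the others keep the name in the file. The supplied table gave no positions, so none are stated. A gene with several probes was represented by the probe with the highest mean over the 16 arrays, which gave 20363 genes, 14496 with a matched symbol and 5867 without. Among called genes with several probes, 39 of 183 at 12 h and 20 of 161 at 18 h had another probe of the opposite sign, and in 0 of them did that other probe pass the test. ATF3 at 12 h was the named gene in that situation.

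Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on all 16 arrays, with 12 residual degrees of freedom and a prior of 2.91. There were 5 comparisons: 6-OHDA against control at each time, the difference between those effects, and 18 h against 12 h within each treatment. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Effects are log2 fold changes with the standard error (SE) of the fit, from 4 arrays per group. The fit treats all arrays as independent. The matching step used the R package data.table (version 1.17.8), the random block used statmod 1.5.0, and the reading and plotting steps used Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

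Before the data were examined, 31 gene lists with 797 genes were written from textbook knowledge of oxidative injury, neuronal and catecholaminergic identity, cell cycle, metabolism and other cell types, and the comparisons, thresholds, alternatives and rule for named genes were fixed. Of the listed genes, 698 were measured, and 17 of these belong to over 1 list. Lists with at least 5 measured genes, 29 of 31, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. The mitochondrially encoded list had 0 measured genes and the Schwann-like list 4. In 129 genes a value was missing on some array, and these were left out of the set tests. Camera asks whether the genes of a list shifted relative to all other genes, with an estimated correlation as an alternative. Fry, also run, asks whether the genes of a list moved 1 way on balance, without comparing them with other genes. The preset correlation treats genes as close to independent, so its adjusted p-values read as too small where genes of a list vary together.

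Named genes follow a rule. For each treatment comparison these are the 10 largest rises and 10 largest falls among called genes whose 4 treated arrays all lay beyond the 4 control arrays, without features named only by a clone, accession or similar number. From each list that passed camera or had a called member, up to 4 members with the smallest p were taken, and those that passed the test are named. For the difference between times and the time comparisons, the 5 largest rises and falls were taken. HMOX1, DDIT3, ATF3, TXNRD1, TH, SLC6A3, SLC18A2, CDKN1A and MKI67 are always given. SLC18A2 did not pass the background filter and was not tested. A few further genes that the rule names are not reported here.

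Each slide held 2 replicates of every group: replicates 1 and 2 lay on slide 1, replicates 3 and 4 on slide 2. Each column of a slide held 1 group, so an effect of the column cannot be told apart from the group. Replicate numbers were checked as pairs by correlating deviations from the group mean across genes. Arrays with the same number correlated at 0.218 to 0.556 in the 12 h comparison, at 0.242 to 0.429 in the 18 h comparison, at 0.334 to 0.558 between the 6-OHDA groups and at 0.0862 to 0.514 between the control groups. Arrays on the same slide with another number also correlated above 0, and arrays on different slides at -0.48 to -0.12. An array was closest to the array with its own number in 2, 4, 4 and 2 of 4 cases, in that order. Slide and replicate number were therefore both fitted as blocks, as alternatives. The design is balanced over slides, so that a slide block leaves log2 fold changes as they are for genes with no missing spot, and changes their error.

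Alternatives fixed with them were quantile normalization, median scaling, the authors' values, no background filter, a filter on all 16 arrays, the mean of all probes of a gene, each probe on its own, the compared groups alone, an eBayes trend with robust variances, array weights, slide and replicate blocks, stricter thresholds and leaving out each array. Alternatives added after the files had been seen were normexp (offset 50) on the raw median signals, the 75th percentile over probes detected on all arrays, spike-in scaling, each slide alone, and set tests with an estimated correlation or fry plus a block. A normexp correction of mean signals, also fixed then, was not run, since the files hold no mean signals. Under a detection share of 50% the percentile over detected probes is the usual choice. The arrays lay between 44.7% and 49.8%, and the percentile over all probes was kept as the main setting because it had been fixed.

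The pipeline was tested on simulated data with 66 or 67 genes changed at each size and the gene-wise spread of these arrays, with values independent between genes. Of genes shifted by 1 on the log2 scale, 73.1% were recovered at 12 h, 80.6% at 18 h and 53.7% to 64.2% in the difference between times. At a shift of 0.5 these shares were 26.9%, 32.8% to 34.3% and 5.97% to 8.96%. Between 3 and 9 unchanged genes were called per comparison, the shifted list was called each time, and 0 of the other lists were. The simulated genes varied independently and without a slide effect, so that 0 does not show how often lists are called falsely on these arrays. On the real arrays, other splits called up to 19 lists at 12 h and up to 19 at 18 h. The number of arrays limits the precision of all values.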

Results

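Gene expression was measured in SH-SY5Y cells, a human neuroblastoma line with catecholaminergic features that serves as a cell model in Parkinson disease research. The cells were controls or had been exposed to 6-hydroxydopamine (6-OHDA), an oxidising dopamine analogue that injures catecholaminergic cells, and were collected at 12 h or at 18 h. Each of the 4 groups held 4 independent replicates, 1 array each, and the labels give no dose of 6-OHDA. The series belongs to work on repurposing the flavonoids quercetin and rutin, and it holds no sample treated with either. On each array 44.7% to 49.8% of 60901 spots were well above background. The 75th percentile of the processed signal over these spots ran from 197 to 353 intensity units. Taken over probes, as used for the scaling, the log2 75th percentile was lower on 6-OHDA than on control arrays. It was 7.29 ± 0.05 against 7.74 ± 0.21 at 12 h and 7.21 ± 0.16 against 7.61 ± 0.10 at 18 h (mean ± SD, n = 4). Both differences had a 2-sided exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give. The 100 brightest probes held 26.5% ± 0.722 of the signal on 6-OHDA arrays and 23.2% ± 1.38 on control arrays at 12 h, and 26.9% ± 0.630 and 24.5% ± 0.804 at 18 h (mean ± SD, n = 4), again with an exact permutation p of 0.0286 each. Treatment and slide both separated the arrays on the first 2 principal components, where the times did not part visibly. On the third (10.2% of variance) the control arrays of 12 h all scored above those of 18 h, and the 6-OHDA arrays of the times overlapped.

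**Figure D1:**
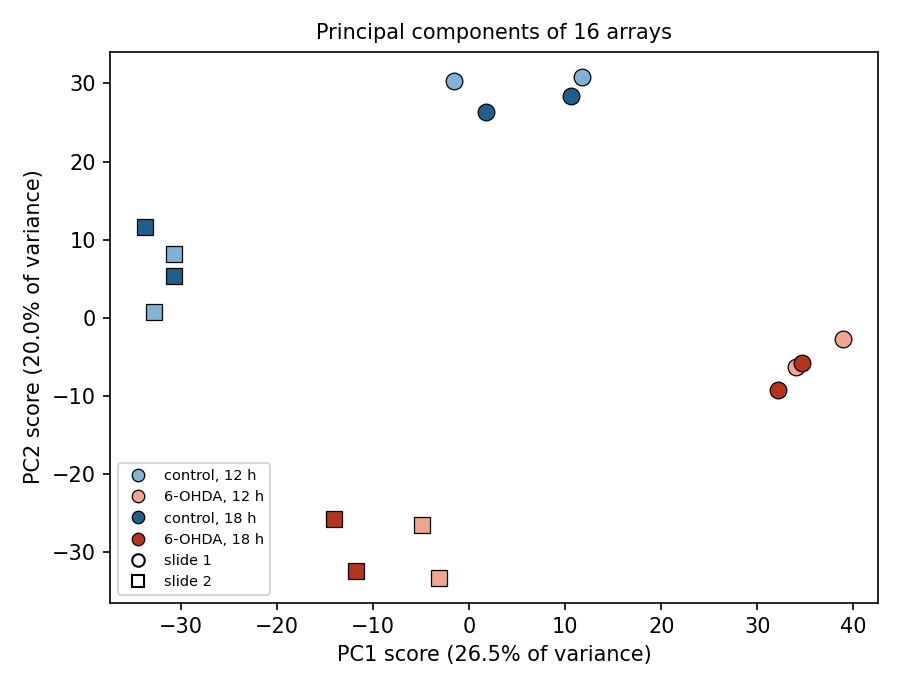
Scores of the 16 arrays on principal components 1 (26.5% of variance) and 2 (20%), computed from the normalised log2 values, with colours for the groups and symbols for the 2 slides. Within each slide the 6-OHDA arrays lie to the right of and below the control arrays.

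The comparison of 6-OHDA with control cells at 12 h asks which genes this toxin changes early. NQO1, a quinone reductase and classic target of the antioxidant transcription factor NRF2, rose by 2.32 ± 0.23 on the log2 scale (SE, n = 4 per group, adjusted p = 9.46e-05). HMOX1, the haem-degrading enzyme induced by oxidative stress, rose by 2.20 ± 0.524 (adjusted p = 0.0281). GDF15, a secreted stress cytokine, rose by 2.19 ± 0.178 (adjusted p = 3.20e-05), and CDKN1A, the cell cycle inhibitor p21, by 1.42 ± 0.314 (adjusted p = 0.0208). The metal-binding metallothionein MT1F fell by 1.99 ± 0.158 (adjusted p = 3.20e-05), and ID1 and ID3, inhibitors of helix-loop-helix transcription factors, fell by 2.05 ± 0.181 and 1.74 ± 0.203 (adjusted p = 3.26e-05 and 0.000344). Genes of cholesterol synthesis fell as well, among them DHCR7, the last enzyme of the pathway, at -0.92 ± 0.117 (adjusted p = 0.000544).

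In total 863 of 20363 genes were called at 12 h, 319 higher and 544 lower with 6-OHDA, and 597 of them carried a matched symbol. Changes of at least 2-fold were seen in 159 genes, 109 higher and 50 lower. In 810 of the 863 the 4 treated arrays all lay beyond the 4 control arrays. The same arrays gave the calls, so this count describes them and is no separate support. The share of calls that were higher was 37.0%, and this split depended on the scaling. It was 8.68% with median scaling, 33.6% with normexp, 46.9% with quantile normalization, 47.6% in the authors' values, 64.0% with the percentile over detected probes and 69.0% with spike-in scaling. Median scaling moved the median of all genes to -0.24 at 12 h and -0.11 at 18 h, and spike-in scaling to -0.11 and -0.12.

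Among the 10 largest rises at 12 h, several genes were not well above background in control cells. For such a gene the change is given as at least N-fold, the mean of the bright group against a mean that takes, on each array of the dim group, the higher of the lowest signal well above background and the gene's own signal. The bound is computed from the processed signal, so it too depends on the background subtraction of that signal. ULBP1, a ligand of the natural killer cell receptor NKG2D, rose at least 4.74-fold, CCKBR, a cholecystokinin and gastrin receptor, at least 4.54-fold, the polycystin family gene PKD1L2 at least 3.70-fold and the growth factor PDGFB at least 2.49-fold (adjusted p = 0.000313, 3.26e-05, 0.000471 and 0.00411). SLC7A11, the cystine transporter of glutathione synthesis, rose by 3.49 ± 0.508 and the NRF2 target OSGIN1 by 2.45 ± 0.319 (adjusted p = 0.00149 and 0.000650), each above background on 2 of 4 control arrays. Their sizes were 2.48 and 1.33 in the authors' values. The phospholipase PLA2G2F, the antisense RNA JRKL-AS1 and PLEKHN1 rose as well (adjusted p = 0.00151, 0.000491 and 0.0218), each above background on 1 of 4 control arrays. The sizes of these too depended on the background step, at 3.63, 3.18 and 2.94 here and 2.05, 1.58 and 1.02 in the authors' values, where PLEKHN1 did not pass (adjusted p = 0.0722). ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.40 ± 0.351 from a level measured on all control arrays (adjusted p = 0.00151).

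ID1, MT1F and ID3 were among the 10 largest falls at 12 h. The synaptic vesicle gene SYNPR fell at least 2.66-fold, the neuronal calcium sensor HPCA at least 2.03-fold, the chemokine CXCL1 at least 1.98-fold and the proton channel gene OTOP1 at least 1.54-fold (adjusted p = 0.00834, 0.0164, 0.000576 and 0.00352). None of these 4 was well above background on any 6-OHDA array. SCML4 fell by 1.86 ± 0.180 and the synaptic adhesion gene IGSF21 by 1.56 ± 0.194 (adjusted p = 8.68e-05 and 0.000491). OTOR fell by 1.75 ± 0.377, and by 0.97 in the authors' values, and was above background on 2 of 4 6-OHDA arrays (adjusted p = 0.0184).

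Stress-response lists shifted up at 12 h. Of 30 measured NRF2 targets, 14 rose and 0 fell, with 21 and 1 adjusted over the list alone. Their median log2 fold change was 0.58 (0.64 on slide 1 and 0.48 on slide 2), with a camera adjusted p of 9.32e-18 and an adjusted p of 0.00947 with an estimated correlation. TXNRD1, which encodes thioredoxin reductase, rose by 1.12 ± 0.190, the NADPH-producing malic enzyme ME1 by 0.92 ± 0.125 and the pentose phosphate enzyme TKT by 0.76 ± 0.0803 (adjusted p = 0.00444, 0.000866 and 0.000257). Of 39 genes of the integrated stress response, 11 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.37, 0.40 and 0.33 on the slides, adjusted p = 7.19e-14, and 0.0266 with an estimated correlation). They included DDIT3, the transcription factor CHOP, at 1.40 ± 0.224, CHAC1, a glutathione-degrading enzyme, at 1.39 ± 0.169, ATF3 at 1.25 ± 0.183 and SESN2 at 0.82 ± 0.110 (adjusted p = 0.00321, 0.000471, 0.00153 and 0.000838). Another ATF3 probe had the opposite sign and did not pass.

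All 29 measured p53 targets had a positive log2 fold change at 12 h, and 11 rose (17 adjusted over the list alone; 0 fell in both; median 0.41 over all arrays and on each slide, adjusted p = 2.28e-19, and 0.0402 with an estimated correlation). Besides CDKN1A these included the death receptor FAS at 1.11 ± 0.213, GADD45A at 0.84 ± 0.116, PHLDA3 at 0.74 ± 0.100 and PLK3 at 0.45 ± 0.0850 (adjusted p = 0.0101, 0.00102, 0.000852 and 0.00871). Of 25 chaperones of the unfolded protein response of the endoplasmic reticulum, 8 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.30, 0.34 and 0.27 on the slides, adjusted p = 1.81e-09, and 0.0539 with an estimated correlation). Examples were HYOU1 at 0.70 ± 0.151, PDIA3 at 0.47 ± 0.0985, CRELD2 at 0.44 ± 0.0860 and XBP1 at 0.44 ± 0.0838 (adjusted p = 0.0176, 0.0166, 0.0107 and 0.00977).

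Among 23 immediate early genes, 4 rose and 0 fell at 12 h (5 and 2 adjusted over the list alone; median 0.05, which turned negative with spike-in and median scaling; 0.23 on slide 1 and -0.01 on slide 2). Camera gave an adjusted p of 0.00870, and 0.305 with an estimated correlation. The 4 were ATF3, MAFF at 0.61 ± 0.102, BTG2 at 0.48 ± 0.0965 and DUSP4 at 0.48 ± 0.108 (adjusted p = 0.00401, 0.0143 and 0.0217 for the last 3). Of 33 autophagy and lysosome genes, 3 rose and 0 fell (also 3 and 0 adjusted over the list alone; median 0.03, negative with normexp, spike-in and median scaling; 0.06 and 0.01 on the slides, adjusted p = 0.0122, and 0.404 with an estimated correlation). These were the autophagy receptor SQSTM1 at 0.98 ± 0.217, GABARAPL1 at 0.92 ± 0.156 and TFEB, a master regulator of lysosomal genes, at 0.81 ± 0.161 (adjusted p = 0.0208, 0.00444 and 0.0124). With normexp neither list passed (adjusted p = 0.181 and 0.705), and without a background filter they had 0.601 and, with the test turned down, 0.626.

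Lipid, metal and proliferation lists shifted down at 12 h. Of 24 cholesterol synthesis genes, 9 fell and 0 rose (19 and 0 adjusted over the list alone; median -0.49, -0.55 and -0.41 on the slides, adjusted p = 1.01e-11, and 0.218 with an estimated correlation). Beside DHCR7, the falls included FDFT1, the squalene synthase, at -0.67 ± 0.101 (adjusted p = 0.00200). Of 8 metallothionein and zinc export genes, 3 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.83, -0.80 and -0.85 on the slides, adjusted p = 6.38e-06, and 0.273 with an estimated correlation). Beside MT1F these were MT1X at -1.41 ± 0.160 and MT1A at -0.65 ± 0.152 (adjusted p = 0.000311 and 0.0267). All 31 genes of G2 and mitosis had a negative log2 fold change (median -0.53, -0.59 and -0.47 on the slides, adjusted p = 9.07e-08, and 0.404 with an estimated correlation). Of these 1 passed the test, PTTG1, the securin of sister chromatids, at -0.69 ± 0.170 (adjusted p = 0.0324; also 1 adjusted over the list alone). With slide as a block 24 of the 31 fell. MKI67, a proliferation marker, had -0.46 ± 0.181 (adjusted p = 0.166, and 0.0347 with slide as a block). Of 35 DNA replication genes 0 rose and 0 fell, with a median of -0.27 (-0.25 and -0.26 on the slides, adjusted p = 0.00454, and 0.745 with an estimated correlation; 12 fell with slide as a block).

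Neuronal and catecholaminergic lists also shifted down at 12 h. Of 28 catecholaminergic genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.22, -0.27 and -0.16 on the slides, adjusted p = 0.000217, and 0.305 with an estimated correlation). They were MAOB, a monoamine oxidase, at -0.80 ± 0.176, the dopamine-forming decarboxylase DDC at -0.78 ± 0.152, the vesicular transporter SLC18A1 at -0.75 ± 0.144 and the noradrenaline transporter SLC6A2 at -0.64 ± 0.159 (adjusted p = 0.0208, 0.0107, 0.00977 and 0.0338). TH, the rate-limiting enzyme of dopamine synthesis, had -0.07 ± 0.198, and the dopamine transporter SLC6A3, above background on 2 of 4 6-OHDA arrays, -0.22 ± 0.342 (adjusted p = 0.889 and 0.765). Of 34 neurite and synapse genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; median -0.16, -0.19 and -0.14 on the slides, adjusted p = 0.0122, and 0.404 with an estimated correlation). These were GAP43, a growth cone protein, at -0.83 ± 0.146 and the neuronal deubiquitinase UCHL1 at 0.34 ± 0.0898 (adjusted p = 0.00560 and 0.0475). Of 14 MYCN and neuroblastoma core genes 1 fell, LMO1 at -0.53 ± 0.130 (adjusted p = 0.0331), and 0 rose (0 rose and 3 fell adjusted over the list alone; median -0.24, -0.26 and -0.19 on the slides, adjusted p = 0.00870, and 0.404 with an estimated correlation). Of these 14 genes 6 also belong to another list, so this list is not independent of the others.

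Energy metabolism and ribosome biogenesis completed the lists that shifted down at 12 h. Of 57 nuclear-encoded respiratory chain genes, 56 had a negative log2 fold change. Of these 2 fell, ATP5MC1 at -0.48 ± 0.112 and NDUFA2 at -0.39 ± 0.0944 (adjusted p = 0.0263 and 0.0288; 14 fell and 0 rose adjusted over the list alone; 13 fell with slide as a block). Their median was -0.22 (-0.21 on each slide, adjusted p = 8.28e-09, and 0.404 with an estimated correlation). It was -0.08 with quantile normalization, -0.10 in the authors' values and -0.12 with detected probes. With spike-ins, normexp and median scaling it was -0.28, -0.33 and -0.41. The size of this shift thus depended on the scaling, and the count of 56 was taken in the main setting alone. Random lists matched on mean expression were not run for these genes. Of 20 glycolysis genes, the glucose transporter SLC2A1 fell by 0.81 ± 0.169 and the aldolase ALDOC by 0.67 ± 0.140 (both adjusted p = 0.0162; 3 fell and 0 rose adjusted over the list alone). The glycolysis median was -0.19 (-0.20 and -0.25 on the slides, adjusted p = 0.00315, and 0.389 with an estimated correlation). Of 30 ribosome biogenesis genes 0 rose and 0 fell, also adjusted over the list alone, with a median of -0.19 (-0.22 and -0.14 on the slides, adjusted p = 0.00452, and 0.571 with an estimated correlation; 6 fell with slide as a block). With quantile normalization the glycolysis, ribosome, neurite and MYCN lists no longer passed (adjusted p = 0.0651, 0.0687, 0.0752 and 0.0651), and in the authors' values the first 3 did not (adjusted p = 0.0592, 0.0606 and 0.105). Of the markers of other cell types, 3 lists were tested and did not pass: adjusted p was 0.882 for 20 mesenchymal genes (median -0.05), 0.757 for 8 epithelial genes (median 0.08, of which KRT19 fell by 0.62 ± 0.132, adjusted p = 0.0174) and 0.288 for 5 leukocyte genes (median 0.11), and 4 Schwann-like genes (median -0.39) were too few for the test. Of these 4, 0 were called, 1 fell with slide and 3 with replicate as a block, so a shift of that list stays open.

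Across all genes the log2 fold changes at 12 h correlated at r = 0.70 between the slides, and 76.3% had the same sign. Slide as a block gave 2509 calls and replicate number as a block 3322, all 863 among them in both cases. Leaving out an array gave 333 to 997 calls, and the number fell by more than 1.5 times without replicate 1, 2 or 3 of the controls (333, 530 and 439) or replicate 1, 2 or 4 of the 6-OHDA group (446, 563 and 413).

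**Figure D2:**
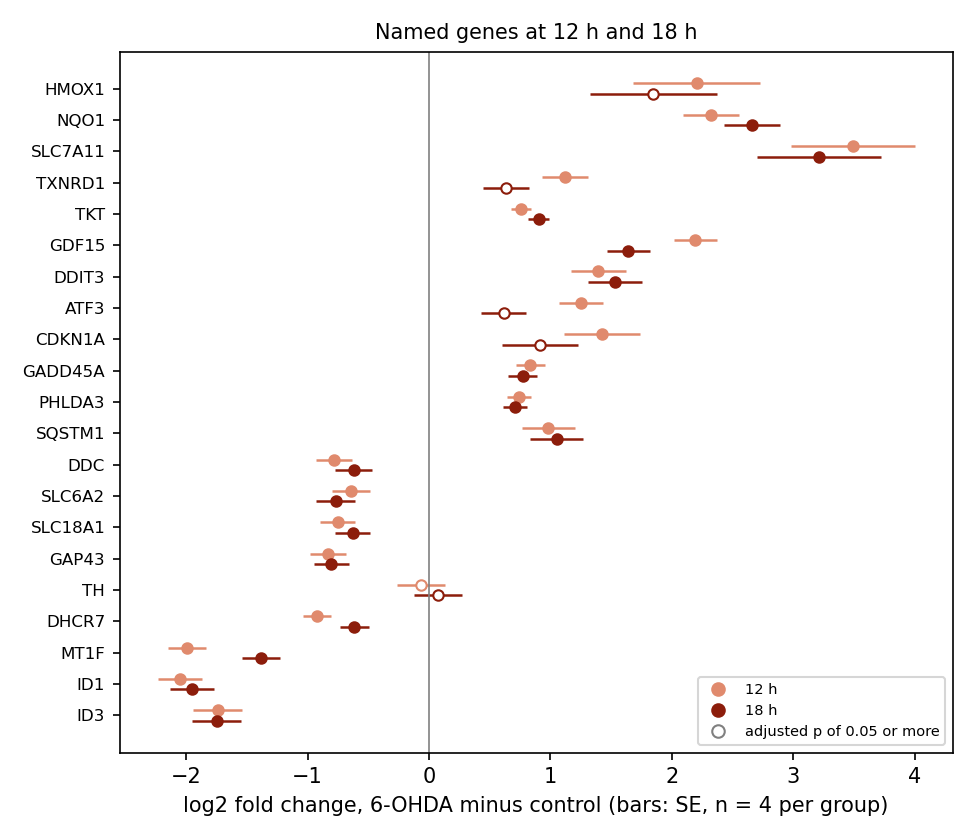
Log2 fold changes (6-OHDA minus control) of 21 named genes at 12 h and 18 h, as estimates from 4 arrays per group with the SE of the fit as bars and open points for an adjusted p of 0.05 or more, as for HMOX1 at 18 h (0.0648). In these values NQO1 and GDF15 lie above 0 and MT1F and ID1 below 0 at both times.

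At 18 h the same comparison asks what 6-OHDA has changed after longer exposure. NQO1 was higher by 2.66 ± 0.230 on the log2 scale (SE, n = 4 per group, adjusted p = 3.78e-05), GDF15 by 1.64 ± 0.178 (adjusted p = 0.000219) and DDIT3 by 1.53 ± 0.224 (adjusted p = 0.00223). ID1 fell by 1.95 ± 0.181, ID3 by 1.75 ± 0.203 and MT1F by 1.38 ± 0.158 (adjusted p = 7.87e-05, 0.000324 and 0.000290). HMOX1 had 1.85 ± 0.524, CDKN1A 0.91 ± 0.314, TXNRD1 0.64 ± 0.190 and ATF3 0.62 ± 0.183, none of which passed (adjusted p = 0.0648, 0.119, 0.0764 and 0.0764). With slide as a block these 4 passed (adjusted p = 0.000216, 0.00213, 0.0219 and 0.0417), as did MKI67, at -0.49 ± 0.181 (adjusted p = 0.147, and 0.0290 with the block).

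In total 732 genes were called at 18 h, 405 higher and 327 lower, and 533 of them carried a matched symbol. Changes of at least 2-fold were seen in 118 genes, 80 higher and 38 lower. In 708 of the 732 the 4 treated arrays lay beyond the 4 control arrays, again a description of calls made on these same arrays. The share of calls that were higher was 55.3%, and 28.4% with median scaling, 43.2% with normexp, 64.1% with the percentile over detected probes and 79.6% with spike-in scaling.

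Many of the largest rises at 18 h were in genes of the 12 h list. JRKL-AS1 rose at least 4.87-fold, PKD1L2 at least 3.66-fold, CCKBR at least 2.61-fold and ULBP1 at least 1.97-fold (adjusted p = 0.00280, 0.000219, 9.41e-05 and 0.00536). CCKBR and ULBP1 were above background on 3 of 4 6-OHDA arrays. SLC7A11 rose by 3.21 ± 0.508, measured above background on 1 of 4 control arrays, PLA2G2F by 2.86 ± 0.530 (3 of 4) and the antisense RNA ZFAT-AS1 by 2.68 ± 0.566 (2 of 4, adjusted p = 0.00360, 0.00953 and 0.0185). The small nucleolar RNA SNORD117, above background on 1 of 4 control arrays, and the germ cell gene TEX19 each rose by 1.88, with an SE of 0.364 and 0.273 (adjusted p = 0.0117 and 0.00207). In the authors' values the rises were 1.72 for SLC7A11, 1.90 for PLA2G2F, 1.44 for ZFAT-AS1, 0.72 for SNORD117 and 1.41 for TEX19.

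Among the largest falls at 18 h, the BMP family ligand GDF10 fell by 2.18 ± 0.349 and was above background on 1 of 4 6-OHDA arrays (adjusted p = 0.00391). SYNPR fell by 1.88 ± 0.445, CABP7 by 1.60 ± 0.386 and PRDM13 by 1.46 ± 0.329, each above background on 2 of 4 6-OHDA arrays (adjusted p = 0.0312, 0.0350 and 0.0251). SCML4 fell by 1.60 ± 0.180 and IGSF21 by 1.56 ± 0.194 (adjusted p = 0.000268 and 0.000626). OTOR fell by 1.60 ± 0.377 (above background on 1 of 4 6-OHDA arrays) and the phospholipase PLCB2 by 1.43 ± 0.303 (3 of 4, adjusted p = 0.0311 and 0.0188). In the authors' values the falls were 1.43 for GDF10, 1.17 for SYNPR, 0.94 for CABP7, 0.79 for PRDM13, 0.95 for OTOR and 0.84 for PLCB2.

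The NRF2 list was again the one with most calls at 18 h: 14 of 30 genes rose and 0 fell (22 and 1 adjusted over the list alone; median 0.63, 0.71 and 0.45 on the slides, adjusted p = 3.12e-16, and 0.0128 with an estimated correlation). Examples were AKR1C3 and CBR3, which reduce reactive carbonyls, at 1.80 ± 0.261 and 1.22 ± 0.154, and TKT, measured on 3 of 4 6-OHDA arrays, at 0.91 ± 0.0867 (adjusted p = 0.00207, 0.000667 and 0.000142). Of 29 p53 targets, 28 had a positive log2 fold change and 9 rose, with 0 falls (16 and 0 adjusted over the list alone; median 0.37, 0.34 and 0.43 on the slides, adjusted p = 2.72e-12, and 0.163 with an estimated correlation). PLK2 had 0.94 ± 0.169, GADD45A 0.77 ± 0.116, PHLDA3 0.71 ± 0.100 and FDXR 0.56 ± 0.116 (adjusted p = 0.00759, 0.00254, 0.00174 and 0.0172). Of 39 integrated stress response genes 4 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.16, 0.20 and 0.14 on the slides, adjusted p = 0.000101, and 0.293 with an estimated correlation). These were GDF15, DDIT3, the transcription factor ATF4 at 0.59 ± 0.113 and SESN2 at 0.46 ± 0.110 (adjusted p = 0.0115 and 0.0324 for the last 2). With slide as a block 8 rose. The chaperones of the unfolded protein response did not pass at 18 h (median 0.05, negative with normexp, spike-in and median scaling, adjusted p = 0.0590). Of these 25 genes 1 rose, DNAJB9 at 0.36 ± 0.0888 (adjusted p = 0.0390; 4 adjusted over the list alone).

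Lists of autophagy, iron handling, proteasome and NF-kB genes shifted up at 18 h. Of 33 autophagy and lysosome genes 4 rose and 0 fell, also adjusted over the list alone (median 0.14, 0.17 and 0.15 on the slides, adjusted p = 0.000292, and 0.338 with an estimated correlation). These were SQSTM1 at 1.05 ± 0.217, GABARAPL1 at 0.92 ± 0.156, the protease CTSL at 0.46 ± 0.117 and the sialidase NEU1 at 0.41 ± 0.106 (adjusted p = 0.0167, 0.00581, 0.0441 and 0.0484). Of 17 iron handling and ferroptosis genes, the ferroptosis suppressor AIFM2 rose by 0.69 ± 0.154 and the ferritin light chain FTL by 0.64 ± 0.102 (adjusted p = 0.0229 and 0.00393; 5 rose and 1 fell adjusted over the list alone; median 0.12, 0.08 and 0.11 on the slides, adjusted p = 0.00824, and 0.514 with an estimated correlation). Of 33 proteasome genes 1 rose, PSMC2 at 0.50 ± 0.0947 (adjusted p = 0.0104; 2 adjusted over the list alone; median 0.12, 0.10 and 0.15 on the slides, adjusted p = 0.00801, and 0.630 with an estimated correlation). With normexp the autophagy, iron and proteasome lists did not pass (adjusted p = 0.202, 0.319 and 0.978), and the proteasome test turned down. With median scaling and spike-ins the proteasome list did not pass either (adjusted p = 0.0728 and 0.119). Of 19 NF-kB and cytokine genes 18 had a positive log2 fold change, and the list passed (median 0.45, 0.62 and 0.20 on the slides, adjusted p = 0.00418, and 0.630 with an estimated correlation). Its called member went the other way: CXCL1 fell at least 1.45-fold (adjusted p = 0.0216; also 1 fall adjusted over the list alone), and with slide as a block 5 members rose. Without a background filter neither the NF-kB list nor the integrated stress response passed at 18 h (adjusted p = 0.284 and 0.129), nor did the autophagy, iron and proteasome lists (adjusted p = 0.173, 0.720 and 0.820). Of 20 mesenchymal markers 0 passed and the list did not (median 0.21, adjusted p = 0.20), although it did with slide as a block (adjusted p = 0.0240). With replicate as a block 2 of these genes rose. The 8 epithelial (median 0.18, adjusted p = 0.590), 5 leukocyte (median 0.09, adjusted p = 0.633) and 4 Schwann-like markers (median -0.26, not tested) had 0 calls, while 1 Schwann-like gene fell with slide and 2 with replicate as a block, and with either block 1 epithelial gene rose and 1 fell.

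Neuronal, catecholaminergic and growth lists were lower at 18 h. Of 28 catecholaminergic genes 4 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.25, -0.34 and -0.15 on the slides, adjusted p = 0.000699, and 0.447 with an estimated correlation). These were SLC6A2 at -0.77 ± 0.159, SLC18A1 at -0.63 ± 0.144, DDC at -0.62 ± 0.152 and the transcription factor HAND1 at -0.40 ± 0.104 (adjusted p = 0.0168, 0.0279, 0.0359 and 0.0465). The arrays of SLC18A1 overlapped between the groups. TH had 0.08 ± 0.198 and SLC6A3 -0.25 ± 0.342 (adjusted p = 0.870 and 0.742). SLC6A3 was above background on 1 of 4 6-OHDA and 2 of 4 control arrays. GAP43 fell by 0.80 ± 0.146 (adjusted p = 0.00826), the 1 call among 34 neurite and synapse genes (1 rose and 9 fell adjusted over the list alone; median -0.28, -0.31 and -0.22 on the slides, adjusted p = 2.84e-05, and 0.293 with an estimated correlation). HEY1, a Notch target, fell by 0.61 ± 0.134 (adjusted p = 0.0223), the 1 call among 27 axon guidance and Wnt or Notch genes (5 adjusted over the list alone; median -0.23, -0.23 and -0.29 on the slides, adjusted p = 0.00326, and 0.0710 with an estimated correlation). The MYCN list, which shares 6 of its 14 measured genes with another list, passed with 0 calls (3 falls with slide as a block; median -0.28, -0.34 and -0.21 on the slides, adjusted p = 0.00326, and 0.447 with an estimated correlation). With that block 8 catecholaminergic, 9 neurite and synapse and 6 axon guidance genes fell, and 1 neurite and synapse gene rose.

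Of 24 cholesterol genes, DHCR7 fell at 18 h by 0.61 ± 0.117 (adjusted p = 0.0112; 3 fell and 0 rose adjusted over the list alone; median -0.21, -0.30 and -0.08 on the slides, adjusted p = 0.00238, and 0.630 with an estimated correlation). SLC2A1 fell by 0.76 ± 0.169 (adjusted p = 0.0225), the 1 call among 20 glycolysis genes, also adjusted over the list alone (median -0.14, -0.15 on each slide, adjusted p = 0.00592, and 0.514 with an estimated correlation). POLR1A, a subunit of RNA polymerase I, fell by 0.35 ± 0.0842 (adjusted p = 0.0339), the 1 call among 30 ribosome biogenesis genes (median -0.13, -0.11 and -0.10 on the slides, adjusted p = 0.00421, and 0.630 with an estimated correlation). DNA replication (median -0.25, -0.30 and -0.16 on the slides, adjusted p = 0.00238) and G2 and mitosis (median -0.21, -0.29 and -0.16, adjusted p = 0.0114) passed with 0 calls, and with an estimated correlation they had an adjusted p of 0.630 and 0.658. A slide block gave 7 and 4 falls, and 1 rise among the DNA replication genes. It also gave 5 falls among the glycolysis, 3 among the cholesterol and 2 among the ribosome biogenesis genes. MT1F and MT1X, at -0.77 ± 0.160 (adjusted p = 0.0167), were the 2 falls among 8 metallothionein and zinc export genes, and that list did not pass at 18 h (median -0.08, 0.06 and -0.37 on the slides, adjusted p = 0.0717).

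Across all genes the log2 fold changes at 18 h correlated at r = 0.496 between the slides, and 67.6% had the same sign. Slide as a block gave 2132 calls and replicate number as a block 3075, all 732 among them in both cases. Leaving out an array gave 298 to 686 calls, and the number fell by more than 1.5 times without replicate 1, 3 or 4 of the controls (487, 298 and 398) or replicate 2 or 4 of the 6-OHDA group (322 and 467).

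**Figure D3:**
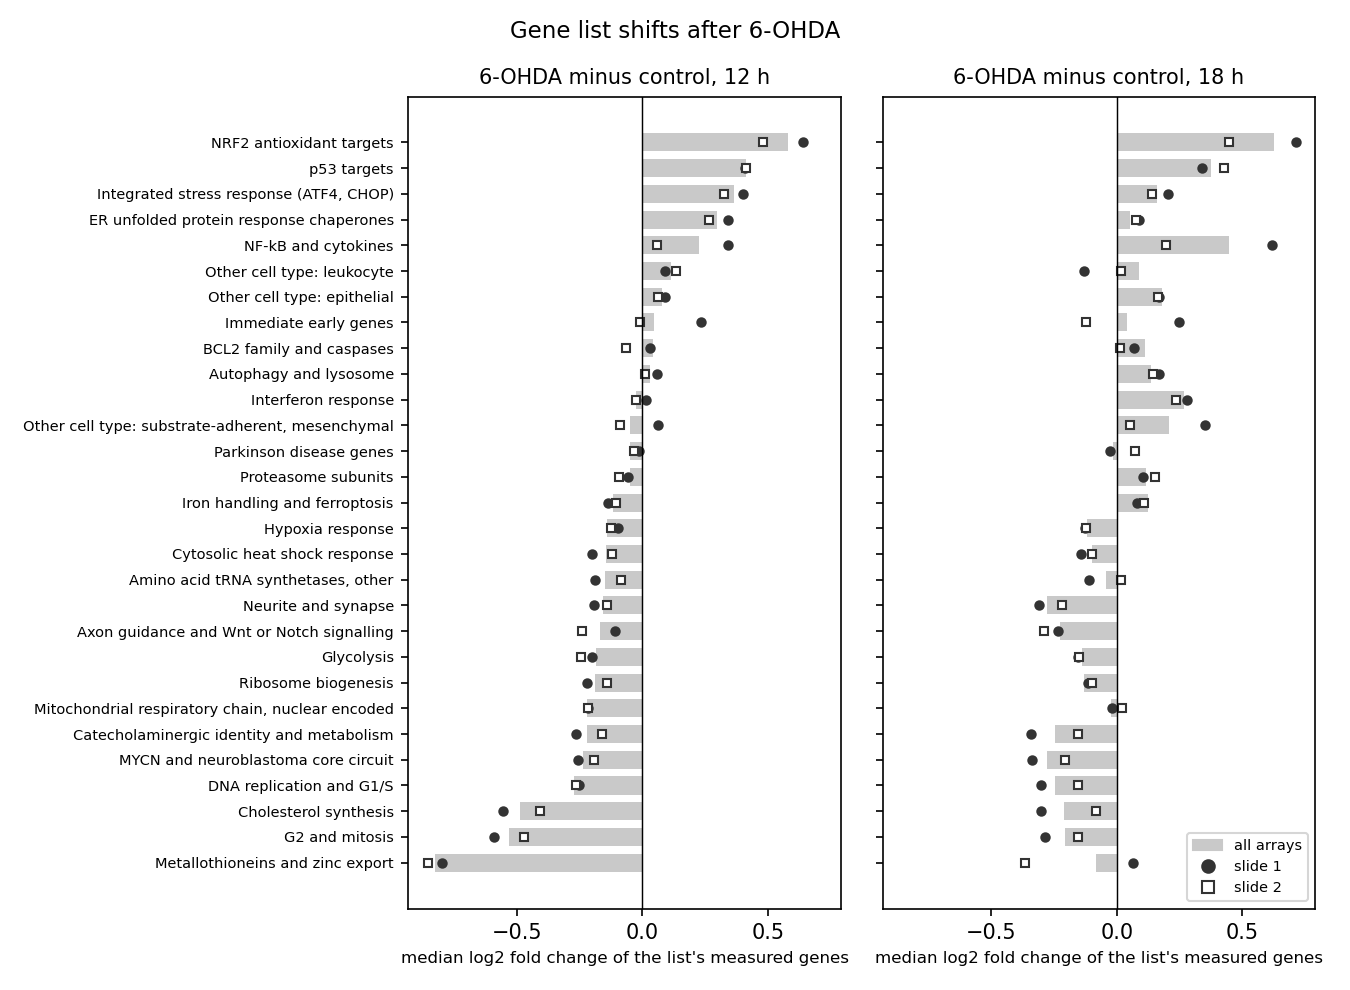
Median log2 fold change (6-OHDA minus control) of 29 gene lists at 12 h and 18 h, with bars for all arrays, circles for slide 1 and squares for slide 2 (2 arrays per group each). The NRF2 list has the highest median at both times (0.58 and 0.63), and the metallothionein median of -0.83 at 12 h is -0.08 at 18 h, with 0.06 on slide 1, while the autophagy and immediate early medians at 12 h change sign with other scalings.

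The overlap asks whether both times changed the same genes. NQO1, GDF15, SLC7A11 and DDIT3 rose and ID1, ID3, MT1F and GAP43 fell at both. Of the genes called, 134 rose and 189 fell at both times, where independence would give 6.34 and 8.74 (Fisher's exact test, p = 1.61e-147 and 1.40e-219), and 0 were called in opposite directions. Of 319 rises at 12 h, 308 had the same sign at 18 h, as did 532 of 544 falls. In the other direction these counts were 385 of 405 and 318 of 327. Across all genes the log2 fold changes of the times correlated at r = 0.681 (rho = 0.593), and at r = 0.887 over 1272 genes called at either. Genes are not independent replicates, and the p-values treat them as such. The times share no arrays but share the 2 slides and, through the common fit, the same estimate of the spread of a gene. A gene with a small spread is thus more readily called at both times, so independence is no strict baseline for these counts. The overlap was not run with a spread from the compared groups alone. The correlation over all genes does not use that spread. The overlap of the calls at 12 h and 18 h was 1003 genes with slide as a block, and it fell by more than 1.5 times without replicate 1 of the controls at 12 h (195), replicate 3 or 4 of the controls at 18 h (174 and 204) or replicate 2 of 6-OHDA at 18 h (187).

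The difference between the 6-OHDA effects at 18 h and 12 h asks whether the response changed with time. A single transcript, XR_242407, passed, with a difference of 1.67 ± 0.198 (SE, n = 4 per group, adjusted p = 0.00934). Its effect was -0.39 at 12 h (adjusted p = 0.131) and 1.29 at 18 h (adjusted p = 0.000219). From 12 h to 18 h it was called lower in control cells and was not called in 6-OHDA cells, so a change of the controls is part of this difference. The transcript was above background on 1 of 4 control arrays at 18 h and 2 of 4 6-OHDA arrays at 12 h. It lies outside the rule for named genes and was chosen after its values were seen. With normexp, spike-in scaling, no background filter, a filter on all 16 arrays or an eBayes trend, in the authors' values and on each slide alone, limma called 0 genes. An unadjusted p under 0.05 was seen in 944 of 20363 genes, no more than chance alone gives at that threshold. Of the genes always given, 0 of 8 passed (lowest adjusted p = 0.999), with differences from -0.64 for ATF3 to 0.14 for TH. Thus HMOX1, ATF3, TXNRD1 and CDKN1A, called at 12 h alone, were not shown to differ between the times.

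With the preset correlation 11 gene lists passed for the difference between times, with 0 called members (1 interferon gene rose with slide as a block). Adjusted over the list alone, 3 metallothionein and zinc export genes, 1 cholesterol gene and 1 interferon gene rose, and 3 unfolded protein response chaperones fell. With an estimated correlation they had adjusted p-values of 0.366 to 0.880, and fry called 0 lists. The median difference was 0.62 for metallothioneins (adjusted p = 2.83e-05), 0.32 for cholesterol synthesis (1.34e-06), 0.30 for G2 and mitosis (adjusted p = 0.00112), 0.24 for interferon response genes (adjusted p = 0.0202), 0.20 for the respiratory chain (adjusted p = 1.55e-08), 0.18 for the proteasome (adjusted p = 0.000103) and 0.12 for iron handling (adjusted p = 0.0352). It was -0.17 for unfolded protein response chaperones (adjusted p = 2.43e-06), -0.10 for the integrated stress response (4.19e-06), -0.06 for p53 targets (0.0257) and -0.04 for neurite genes (0.0326). The p53 and neurite lists did not pass with median scaling (adjusted p = 0.0741 for both), spike-ins (0.0855 and 0.0731) or no background filter (0.231 and 0.310), and the proteasome list did not with quantile normalization (0.0617) or in the authors' values (0.0674). The p53 and neurite medians turned positive with median scaling, which moved the median of all genes to 0.14. The iron list did not pass with slide or replicate as a block (adjusted p = 0.0739 and 0.0597) or with normexp, quantile, median or spike-in scaling or the authors' values (0.0554 to 0.238). With slide as a block the NF-kB list (adjusted p = 0.0226) and the mesenchymal markers (adjusted p = 0.0473) passed too.

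Comparing 18 h with 12 h in control cells asks which genes differ between the times without the toxin. On each slide these groups lay in different columns, so an effect of the column cannot be told apart from time here. ARC and EGR1, immediate early genes induced by stimulation, were higher at 18 h by 1.31 ± 0.118 and 1.16 ± 0.134 (SE, n = 4 per group, adjusted p = 0.000277 and 0.00313). LNCRNA-IUR was lower by 1.29 ± 0.205, the nucleotide receptor P2RY6 had -0.75 ± 0.117 and the sulfotransferase CHST8 -0.71 ± 0.111 (all adjusted p = 0.0428). Outside the rule and chosen after their values were seen are AK124233 at 0.85 ± 0.133 (adjusted p = 0.0428) and XR_242407 at -1.12 ± 0.140 (adjusted p = 0.00603), the latter above background on 1 of 4 arrays at 18 h. These 7 genes were all the calls, with 1870 at an unadjusted p under 0.05. ARC was the fall among immediate early genes in the treatment comparison at 18 h, at -0.51 ± 0.118 (adjusted p = 0.0289).

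Immediate early genes were the list that shifted up in control cells (median 0.25, adjusted p = 4.34e-08, and 0.0467 with an estimated correlation, or 0.0862 with slide as a block too). In it 2 genes rose, and 5 adjusted over the list alone. The 9 lists that shifted down were G2 and mitosis (median -0.40, adjusted p = 3.47e-08), mesenchymal markers (median -0.31), interferon response (median -0.20, adjusted p = 0.0301), cholesterol synthesis (median -0.15), DNA replication (median -0.15, adjusted p = 0.0206), the proteasome (median -0.12, adjusted p = 0.000547), iron handling (median -0.12, adjusted p = 0.0317), autophagy (median -0.11) and the respiratory chain (median -0.06). Lists without a value had an adjusted p of 0.0188. All 9 had an adjusted p of 0.962 with an estimated correlation and 0 called members, though 3 genes of G2 and mitosis fell with slide as a block and 1 interferon gene adjusted over the list alone. Quantile normalization ended the calls for mesenchymal markers (adjusted p = 0.0512), DNA replication (0.0669), cholesterol synthesis (0.141), autophagy (0.195), iron handling (0.220) and the respiratory chain (0.576). With slide as a block 31 genes were called, and the count of 7 became 3 or 4 when an array was left out, whichever it was.

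In 6-OHDA cells, EGR1 was higher at 18 h than at 12 h by 0.92 ± 0.134, and CRELD2, a protein of the endoplasmic reticulum stress response, was lower by 0.59 ± 0.0860 (SE, n = 4 per group, adjusted p = 0.0190 for both). Outside the rule and chosen after their values were seen are 4 transcripts. ENST00000430550, not well above background at 12 h, was at least 2.76-fold higher (adjusted p = 0.00337), ENST00000467688 was higher by 1.04 ± 0.148 (adjusted p = 0.0190), ENST00000465511 by 0.86 ± 0.113 and ENST00000495104 by 0.75 ± 0.0953 (both adjusted p = 0.0105). These 6 were all the calls, with 1318 genes at an unadjusted p under 0.05. Of the genes always given, 0 of 8 passed in 6-OHDA cells (lowest adjusted p = 0.711, from -0.54 for HMOX1 to -0.06 for TH) and 0 of 8 in control cells (lowest adjusted p = 0.388, from -0.65 for DDIT3 to 0.33 for ATF3).

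The integrated stress response shifted down in 6-OHDA cells from 12 h to 18 h (median -0.21, adjusted p = 8.55e-12, and 0.0512 with an estimated correlation), as did the unfolded protein response chaperones (median -0.19, adjusted p = 2.07e-11, and 0.0512; 1 fell, and 6 adjusted over the list alone). Lower too were p53 targets (median -0.17, adjusted p = 2.51e-07, and 0.336 with an estimated correlation), DNA replication (median -0.12; 0.000987 and 0.941), axon guidance (median -0.11; 0.0232 and 0.122) and neurite genes (median -0.04; 0.00756 and 0.716). Metallothioneins had a median of 0.43 (adjusted p = 0.000193, and 0.458 with an estimated correlation), immediate early genes 0.18 (9.99e-05 and 0.121), cholesterol synthesis 0.16 (0.000393 and 0.716) and the respiratory chain 0.11 (9.79e-06 and 0.723). The last 3 turned negative with spike-in scaling, which moved the median of all genes to -0.24. Adjusted over the list alone, 6 integrated stress response genes and 1 neurite gene fell, and 3 metallothionein and zinc export, 4 immediate early and 1 cholesterol gene rose. The axon guidance list did not pass with normexp (adjusted p = 0.111) or in the authors' values (adjusted p = 0.126). With slide as a block 18 genes were called, and G2 and mitosis passed too (adjusted p = 0.00283). Leaving out an array gave 2 to 11 genes, with more than 1.5 times fewer without replicate 1 or 2 at 12 h (3 each) or replicate 2, 3 or 4 at 18 h (3, 2 and 3) and more without replicate 4 at 12 h (11).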

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

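The column test of the metallothioneins, both tests of the dim genes, the spike-in test of the 75th percentile and the test of the signal share as its whole difference were chosen after the result was seen.

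The difference between the 6-OHDA effects at 18 h and 12 h passed the test for the transcript XR_242407 (1.67), which in control cells was itself lower at 18 h than at 12 h. The difference passed for 11 gene lists, none of them with an estimated correlation. Their median differences were 0.62 for metallothioneins, 0.32 for cholesterol synthesis, 0.30 for G2 and mitosis, 0.24 for interferon response, 0.20 for the respiratory chain, 0.18 for the proteasome and 0.12 for iron handling. They were -0.17 for unfolded protein response chaperones, -0.10 for the integrated stress response, -0.063 for p53 targets and -0.044 for neurite genes, and with median scaling the last 2 were above 0.

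In single groups of 4 arrays, 1 array lay far from the others in 21 of 333 sets of values of named genes (6.31%), where chance gives about 1 in 20. The value below is the gap to the nearest array as a share of the group's range. In control cells at 12 h, replicate 4 was high for ID3 (0.912), ULBP1 (0.890), TH (0.882) and HYOU1 (0.848) and low for SLC6A2 (0.959), and replicate 1 was low for SLC18A1 (0.948). In 6-OHDA cells at 12 h, replicate 3 was high for DUSP4 (0.892), FAM162A (0.890) and XBP1 (0.881), replicate 2 was high for FAS (0.881), replicate 1 was low for HPCA (0.900) and replicate 4 was low for BCL2L11 (0.879). In control cells at 18 h, replicate 4 was low for SLC6A2 (0.879) and high for ULBP1 (0.832), replicate 3 was low for OAS3 (0.874), replicate 1 was high for PINK1 (0.847) and replicate 2 was low for ATF4 (0.833). In 6-OHDA cells at 18 h, replicate 2 was high for GABARAPL1 (0.909), and replicate 3 was high for HEY1 (0.868) and low for MT1F (0.867) and FTL (0.855).

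The metallothionein and zinc export list had a median of -0.83 at 12 h. A trend with intensity was argued against by 10000 random lists matched on mean expression, of which 0% reached that median, with 95% of them between -0.25 and 0.07. The medians were -0.80 on slide 1 and -0.85 on slide 2. These do not test a difference between the slides, which cancels in this design because each slide held 2 arrays of every group. A gradient rising or falling across the columns of a slide was argued against by the control arrays 2 columns apart, which had a median difference of -0.17. Those arrays also differ in time, 18 h against 12 h, so a gradient offset by a change with time is not excluded. An effect of a single column cannot be told apart from the group, since each column held 1 group, and signal shared between the near-identical metallothionein probes was not tested, so both stay open beside an effect of 6-OHDA.

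The 10 largest rises at 12 h were mostly in genes at or below background in control cells. Background subtraction as the source of the calls was argued against by 9 of the 10 genes being called higher both with normexp and in the authors' values. Inflated sizes fit the values: the median log2 fold change of the 10 genes was 3.31 here, 1.53 in the authors' values (46.2% of it) and 1.08 with normexp (32.6%), and at 18 h it was 2.67, 1.43 and 1.01. The sizes of these changes therefore depend on the background step. The bounds given as at least N-fold come from the same background-subtracted signals, so they depend on it too and are no lower limit for other processings. A rise after 6-OHDA stays open as the biological explanation.

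The 75th percentile of signal was lower on 6-OHDA arrays, by -0.45 at 12 h and -0.40 at 18 h on the log2 scale. Relative to the spike-ins the differences were -0.06 (exact permutation p = 0.771) and -0.11 (p = 0.743), and against the whole difference of the 75th percentile the exact permutation p was 0.2 and 0.314, so a lower labelling yield and less RNA signal cannot be told apart here because the spike-ins varied between arrays. A larger share of signal in the 100 brightest probes, by 3.33 percentage points at 12 h and 2.40 at 18 h (exact permutation p = 0.0286 for both), may contribute. As the whole difference it was argued against, since the log2 share left to the other probes differed by -0.0638 at 12 h and -0.0466 at 18 h. An effect of 6-OHDA on the cells' RNA stays open and was not tested.

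Other splits of the same arrays were run for each count. For genes, 1 of 35 splits, the real one itself, called as many as the real split at 12 h (863, highest other 1), at 18 h (732, highest other 1) and for time in control cells (7, highest other 0). This met the bound set beforehand for arguing against chance, and it is the smallest share that 35 splits can give. It holds if the arrays of a comparison are exchangeable. Arrays resembled others on their slide, so these splits alone do not exclude chance. For the difference between times 4 of 100 splits, the real one among them, called as many as the real split (1, highest other 62). That share met the same bound, but the split with 62 genes points to a structure of the samples. Besides, 8 other settings, normexp and the authors' values among them, called 0 genes. Chance is therefore not excluded, and the single call is left open. For time in 6-OHDA cells that bound was not met: 2 of 35 splits called as many as the 6 real genes, and the split by slide called 894, which points to a structure of the samples, with 18 genes called with slide as a block. For gene lists chance cannot be excluded: 6 of 35 splits had as many lists at 12 h (16, highest other 19) and 6 of 35 at 18 h (16, highest other 19). For the difference between times 29 of 100 did (11, highest other 18), for time in control cells 7 of 35 (10, highest other 14) and for time in 6-OHDA cells 17 of 35 (10, highest other 20). The split by slide gave 13 lists at 12 h, 17 at 18 h, 13 for time in control cells and 20 for time in 6-OHDA cells. If replicate numbers pair the arrays, 8 splits part all 4 pairs, and the highest other count among these was 0 genes at 12 h, 18 h and for time in 6-OHDA cells. For lists it was 18 at 12 h, 17 at 18 h, 5 for time in control cells and 7 for time in 6-OHDA cells, the last 2 below the real 10. For genes and lists alike, 8 splits are too few for a share that could exclude chance.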

How the results depend on the processing

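Chosen after the files had been seen were normexp, the percentile over detected probes, spike-in scaling, each slide alone and the set tests that combine an estimated correlation or fry with a block. Of 162 results of named genes, 143 passed the test, and all 128 that could be tested with a filter on all 16 arrays kept their direction and side of the threshold. The number that stopped passing was 0 with slide, replicate or random blocks and array weights, 3 with the mean of all probes, 4 with an eBayes trend, 10 with quantile normalization, 11 with detected probes, 20 with normexp and 20 in the authors' values, 35 with median scaling, 61 without a filter, 62 (of 161) with the compared groups alone, 93 on slide 1, 104 with spike-ins and 109 on slide 2. Leaving out 1 array in turn left 1004 of 1304 gene results as they were, ended 292, added 5 and reversed 3. Reversed genes were all uncalled. In 6-OHDA against control at 12 h, TH had 0.0049 with normexp, 0.031 with detected probes and -0.12 to 0.028 when an array was left out (0.028 without control replicate 4). SLC6A3 had 0.14 with normexp. In 6-OHDA against control at 18 h, SLC6A3 had 0.18 with normexp and -0.55 to 0.053 when an array was left out (0.053 without 6-OHDA replicate 2). TH had -0.026 with median scaling, -0.032 with spike-ins, -0.13 with array weights, -0.072 on slide 2 and -0.15 to 0.22 when an array was left out (-0.15 without control replicate 2). For these genes the cause was not tested.

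For 6-OHDA against control at 12 h the 863 calls became 3226 with normexp, 1912 with median scaling, 71 with spike-ins, 439 without a filter on dim probes, 440 with the compared groups alone, 2721 with array weights, 2509 with slide, 3322 with replicate and 3028 with a random replicate block, 125 on slide 1 and 112 on slide 2, 159 with a log2 fold change of at least 1 and 217 at an adjusted p below 0.01. Leaving out an array gave 333 to 997. For 6-OHDA against control at 18 h the 732 calls became 1805 with normexp, 348 with median scaling, 1193 with detected probes, 49 with spike-ins, 243 without a filter, 171 with the compared groups alone, 1318 with array weights, 2132 with slide, 3075 with replicate and 2715 with a random replicate block, 208 on slide 1 and 69 on slide 2, 118 with a log2 fold change of at least 1 and 178 at an adjusted p below 0.01. Leaving out an array gave 298 to 686. The overlap of the calls at 12 h and 18 h, 323 genes, became 1091 with normexp, 43 with spike-ins, 123 without a filter, 758 with array weights, 1003 with slide, 1549 with replicate and 1286 with a random replicate block, 76 on slide 1 and 44 on slide 2, and 174 to 304 when an array was left out.

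For the difference of the 6-OHDA effect between 18 h and 12 h the 1 call became 0 with normexp, spike-ins, the authors' values, no filter, the filter on all 16 arrays, the eBayes trend, slide 1 and slide 2, and 2 with slide or a random replicate block. Leaving out an array gave 1 to 2 (2 without replicate 3 of the controls or replicate 1 of 6-OHDA at 18 h). For 18 h against 12 h in control cells the 7 calls became 4 with normexp, the authors' values and a log2 fold change of at least 1, 3 with median scaling, no filter, every probe on its own and an adjusted p below 0.01, 2 with the compared groups alone, 0 with spike-ins and on either slide, 93 with array weights, 31 with slide, 73 with replicate and 22 with a random replicate block, and 3 to 4 when an array was left out. For 18 h against 12 h in 6-OHDA cells the 6 calls became 1 with median scaling, no filter and an adjusted p below 0.01, 2 with a log2 fold change of at least 1, 0 with spike-ins, the compared groups alone and either slide, 18 with slide, 50 with replicate and 54 with a random replicate block, and 2 to 11 when an array was left out. Stricter thresholds, the compared groups alone and single slides lower counts by their construction. For every other change of a count named here the cause was not tested.

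For the gene lists at 12 h, 16 passed, 3 with an estimated correlation, 6 with that and slide, and 0 with that and a replicate block. Those 6 shared an adjusted p of 0.0475. At 18 h 16 passed, and 1, 0 and 0 in those settings and 6 with fry. For the difference of the 6-OHDA effect between 18 h and 12 h 11 passed, and 0, 0 and 0 in those settings, 0 with fry and 0 with fry and slide. For time in control cells 10 passed, and 1, 0 and 0 in those settings, 1 with fry, 3 with fry and slide, 4 with quantile normalization, 4 with spike-ins, 6 in the authors' values and 5 on slide 2. For time in 6-OHDA cells 10 passed, and 0, 0 and 0 in those settings, 3 with fry and 3 with fry and slide. When an array was left out, 12 to 17 lists passed at 12 h, 15 to 19 at 18 h, 7 to 14 for the difference, 5 to 10 for time in control cells and 7 to 13 for time in 6-OHDA cells. The lowest values came without replicate 3 of the controls at 18 h for the difference (7), and without replicate 1 or 2 of the controls at 12 h (5 each) or replicate 3 or 4 of the controls at 18 h (6 and 5) for time in control cells. For these list counts the cause was not tested. The normexp correction of mean signals was not run. With fewer than 50% of spots well above background, folds of dim genes are limited by the background step.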

Other observations

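The test of the fatty acid genes was given a spread requirement after its value was seen, and no other test in this part was chosen that late.

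Several gene groups that did not pass the set test held called genes. Of 20 hypoxia response genes at 12 h, 3 fell and 0 rose, also adjusted over the list alone: EGLN3, an oxygen-sensing prolyl hydroxylase, by 0.75 ± 0.189, NDRG1 by 0.52 ± 0.105 and FAM162A by 0.32 ± 0.0826 (adjusted p = 0.0365, 0.0128 and 0.0403). The list had a median of -0.14 at 12 h (adjusted p = 0.0816) and -0.12 at 18 h (adjusted p = 0.259), with 0 calls at 18 h. Of 27 axon guidance and Wnt or Notch genes, HEY1 fell at 12 h by 0.61 ± 0.134 and the semaphorin co-receptor PLXNA4 by 0.45 ± 0.0947 (adjusted p = 0.0208 and 0.0166), with 4 falls adjusted over the list alone and a list median of -0.17 (adjusted p = 0.115). Of 17 iron handling genes, HMOX1 and AIFM2, the latter by 0.85 ± 0.154 (adjusted p = 0.00705), rose at 12 h, with 4 rises adjusted over the list alone. That list's median was -0.12, its mean 0.13 and its test up (adjusted p = 0.540).

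Of 17 interferon response genes, OAS3, an antiviral oligoadenylate synthetase, fell by 0.52 ± 0.0938 at 12 h and 0.37 ± 0.0938 at 18 h (adjusted p = 0.00705 and 0.0411). The list's median was -0.02 at 12 h (adjusted p = 0.715), above 0 with quantile normalization and with detected probes, and 0.27 at 18 h (adjusted p = 0.0784, and 0.00161 with slide as a block). Of 19 NF-kB genes, CXCL1 fell at 12 h, and the list had a median of 0.23 (adjusted p = 0.115, and 0.0113 with slide as a block). Of 26 BCL2 family and caspase genes, the pro-apoptotic BCL2L11 fell by 0.41 ± 0.0852 at 12 h and the pro-apoptotic BAK1 rose by 0.45 ± 0.107 at 18 h (adjusted p = 0.0166 and 0.0326). The list's median was 0.04 at 12 h (adjusted p = 0.256), below 0 with normexp, spike-ins and median scaling, and 0.11 at 18 h (adjusted p = 0.157).

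Of 23 Parkinson disease genes, UCHL1 rose at 12 h and PINK1, a kinase of mitochondrial quality control, rose by 0.40 ± 0.0963 at 18 h (adjusted p = 0.0330). The list's median was -0.05 at 12 h and -0.02 at 18 h while its test pointed up (adjusted p = 0.733 and 0.350), and both medians were above 0 with quantile normalization, detected probes and in the authors' values. Of 22 heat shock genes, the mitochondrial chaperone HSPE1 fell by 0.44 ± 0.115 at 12 h (adjusted p = 0.0439), with list medians of -0.15 at 12 h and -0.10 at 18 h (adjusted p = 0.171 and 0.20). Of 14 tRNA synthetases outside the integrated stress response list, YARS1 rose by 0.53 ± 0.136 at 12 h and LARS1 fell by 0.64 ± 0.138 at 18 h (adjusted p = 0.0396 and 0.0197), with list medians of -0.15 and -0.04 (adjusted p = 0.327 and 0.157). Of 23 immediate early genes, MAFF rose by 0.54 ± 0.102 at 18 h (adjusted p = 0.0104) beside the fall of ARC, with a list median of 0.04 (adjusted p = 0.270), below 0 with normexp, spike-ins and median scaling. The respiratory chain list had a median of -0.03 at 18 h (adjusted p = 0.497), above 0 with detected probes, and the proteasome list -0.05 at 12 h (adjusted p = 0.481), above 0 with quantile normalization, detected probes and in the authors' values.

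Fitting slide as a block called more genes of most of these lists. At 18 h 4 interferon genes rose and 1 fell, 5 rose and 2 fell in the BCL2 family and caspase list, 5 Parkinson disease genes rose, 4 immediate early genes rose and 3 fell, 1 heat shock gene rose and 4 fell, and 1 hypoxia and 1 tRNA synthetase gene fell. The tRNA synthetase count at 18 h was the same without the block. At 12 h 6 hypoxia, 6 axon guidance, 3 interferon and 4 heat shock genes fell, 4 iron handling genes rose, 1 NF-kB gene rose and 1 fell, 1 BCL2 family gene rose and 2 fell, 2 Parkinson disease genes rose and 1 fell, and 1 tRNA synthetase gene rose and 2 fell.

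ID1 and ID3 are targets of BMP and SMAD signalling, and lower BMP signalling may account for their fall, as a hypothesis. Of 14 further targets listed before their values were seen, 11 were measured, and at 12 h 0 rose and 2 fell, ID2 by 1.30 ± 0.209 and ATOH8 by 1.35 ± 0.312 (adjusted p = 0.00333 and 0.0254). Their median was -0.34 at 12 h, a value that 0.06% of 10000 matched random lists reached. At 18 h it was -0.10 (12.1% of such lists), where ID2 fell by 1.31 ± 0.209 (adjusted p = 0.00390). The times therefore leave the hypothesis undecided.

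Cholesterol and fatty acid synthesis share SREBP transcription factors, and a fall of both pathways could be a wider change of lipid synthesis, as a hypothesis. Of 13 fatty acid genes listed before their values were seen, all were measured, and at 12 h 0 rose and 2 fell, ACACA by 0.74 ± 0.112 and FASN by 0.50 ± 0.129 (adjusted p = 0.00214 and 0.0397). Their median was -0.20 at 12 h, reached by 4.21% of matched random lists, and -0.18 at 18 h (1.46%), where SREBF1 fell by 0.93 ± 0.206 and ACACA by 0.65 ± 0.112 (adjusted p = 0.0223 and 0.00627). The bound stated beforehand as speaking against the hypothesis, a 12 h median above the lowest 2.5% of random lists (-0.22), was met, but by less than the median's SE of 0.0956. The requirement to exceed that spread was applied after the value was seen, and the hypothesis is left undecided.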
